A study of Mus musculus with 8 samples.

How the data were processed

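The series measured RNA m5C in liver of male mice. Per the labels, total RNA was extracted with TRIzol and libraries were made with the EZ RNA Methylation Kit, a bisulfite conversion kit; the labels also speak of immunoprecipitated and input libraries, while the tables hold conversion calls per cytosine. The aligner and site caller are not given in the sources used here, and the submitters' processing notes name only the build mm10. The 8 libraries were grouped by their library names into db (db_1 to db_4) and db_C (db_C2 to db_C5). The tables speak of case and control and do not name the libraries of each arm. Of 116 shared sites whose case value rests on 1 library and that db_1 lists, 116 carried db_1's own coverage and level, against 5 of 196 for the control arm, so db_1 was taken as a library of the case arm. No strain was assigned to any library name.

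The deposited db_1 table gives read counts per cytosine: reads covering it, reads with C and mutated reads. Its level is a fraction that the authors computed as reads with C over coverage, less mutated reads; this was recomputed within 0.001 for 21162 of its sites. Its p-value for the methylated state and the adjusted p-value (at most 0.0094 in this table) are the authors', and the formula of the deposited score was not given in the sources used here. The lowest coverage in that table was 10, the lowest level 0.2 and the lowest number of C reads 8; 18 of its lines were empty and were left out. The 3 comparison tables give, per the file headers, for each arm the mean coverage and mean C reads over the libraries that list a site (rounded by the authors, so scores and not raw counts), the mean level as a fraction with SD and SEM (both divided by n), the number of libraries and a combined p-value. The deposited table of shared sites adds a log2 ratio of the control level over the case level, which matched a recomputation within 0.0005, and a p-value of a test that was not given in the sources used here. The largest p-value listed there was 0.0499985, so only sites below 0.05 in the authors' test are in it, and its adjusted p-values equal a Benjamini-Hochberg adjustment over the listed sites within 1.43e-05. At 2152 sites the deposited p-value was 0, among them 1532 of the 1533 sites with equal levels of 1, so it was not used to call sites. No position occurred in more than 1 comparison table.

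Gene symbols and regions were taken from the files. Of 4365 symbols 4144 (94.9%) were found in the RefSeq table of GRCm38.p6, which was used for names and gene classes only. The boundaries in that table held 9.29% of the db_1 sites of matched genes; positions are therefore printed as the files give them, with no build assigned. A site was called clustered when another site of the same table and strand lay within 10 bases.

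Arm-only sites were counted with exact binomial 95% intervals, which also treat sites as independent. Regions were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment, treating sites as independent. The design had fixed a logistic model across libraries for shared sites; the tables give arm means only, so the pooled-read alternative written there was used, a two-sided Fisher exact test on mean reads times the number of libraries at coverage of at least 10 in both arms, with Benjamini-Hochberg adjustment and a threshold of 0.05. A call also needed the pooled reads and the mean levels to differ in the same direction; this was added after the values were seen and removed 19 sites. Pooled reads weigh deep libraries more, so a call can rest on a small difference of mean levels. The deposited SD divides by n: at all 923 case sites in 2 libraries, 1 of them db_1, it equals the distance of db_1 from the mean within 0.0015. In 4 libraries 1139 of 4386 such sites, and in 3 libraries 284 of 741, had an SD below the smallest possible with a divisor of n - 1, and 0 below the smallest possible with n. The SDs were therefore put on n - 1 everywhere here, in the control arm by the same rule. limma's moderated test was run from the means, these SDs and the library numbers at the 7552 sites with at least 2 libraries in each arm, and was also added after the values were seen. The 22 gene lists, 578 genes, were fixed before the data were examined, as were the design, the rule for named genes and the alternatives not said to be added. Of the list members, 4 go by another symbol in the files (G6pc1, Hc, Atp5f1a, Atp5f1b) and were matched after the values were seen. Lists were tested by two-sided Fisher exact tests of genes with case-only against genes with control-only sites. Genes with both count on both sides, genes with shared sites alone do not enter, and genes are not independent replicates.

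Named genes were the 10 with the most case-only and the 10 with the most control-only sites, up to 3 per lipid, bile acid, lipoprotein and glucose list with the most sites, the 10 largest called rises and falls at shared sites, the 10 highest sites of db_1 at coverage of at least 30, its 10 richest genes, and every m5C writer, eraser or reader with a site. Some genes that this rule takes are not reported here.

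The tests were tested on simulated data drawn from the depths of the 7552 shared sites with at least 2 libraries per arm, with 200 sites changed. With binomial noise alone, the Fisher test recovered 45.9% of sites changed by 0.1 and 93.4% of those changed by 0.3, and called 0.0408% of unchanged sites. With the spread between libraries added it recovered 56.0% and 93.4% and called 18.1% of unchanged sites. The spread added was the arm's median SD at every site, which already holds read sampling, and reads were drawn on top. No shift of a whole library was simulated, so these rates need not hold for the data. limma recovered 22.0% and 78.0% in the first case and 0% and 39.6% in the second, calling 0.0816% and 0.0136% of unchanged sites.

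Alternatives were coverage of at least 20 and 30, a level of at least 0.2, no clustered sites, matching within 10 bases, no mitochondrial, ribosomal, transfer and small RNA genes, genes in place of sites, a logistic model of the pooled reads, a difference of at least 0.1, means in place of medians, other backgrounds and site minimums for the lists, a window of 2 bases, and leaving out db_1. In the data used here, db_1 was the only library whose value could be taken out of the arm mean. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Sequence context outside the windows of the db_1 table was not analysed here.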

Results

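RNA 5-methylcytosine (m5C) was measured in 8 libraries of mouse liver RNA, 4 named db and 4 named db_C. RNA was treated with a bisulfite kit, which converts unmodified cytosine so that a cytosine still read as C is scored as methylated. The m5C level of a site is the share of its reads with C. The series set livers of db/db mice, which lack a working leptin receptor and become obese and diabetic, beside livers of C57BL/6J mice, with hepatic lipid metabolism as its theme. The labels do not say which mice each library name stands for, so the arms are called case and control here, as in the authors' deposited tables.

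Of single libraries, only db_1 had a table of its own among those used here, which listed 21164 sites in 3180 genes at a median coverage of 36 reads (quartiles 20 and 68). The other tables held arm means. They listed 7013 sites found only in the case arm (median coverage 21 reads), 4204 found only in the control arm (24 reads) and 10243 found in both (53 reads in case, 76 in control). A site entered an arm-only table with at least 2 libraries. Every site of db_1 had coverage of at least 10 and a level of at least 0.2, so an absent site may have been too shallow or under that level. Positions are given as in the files; the processing notes name mm10, but 9.29% of 17603 db_1 sites lay inside their gene's GRCm38.p6 boundaries, so the build of the positions was not established. Binomial intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

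The first comparison asked which sites were listed in one arm alone. Case-only sites outnumbered control-only sites by 7013 to 4204, or 62.5% case-only (exact 95% interval 61.6 to 63.4). Most of the excess lay outside annotated genes, with 2939 case-only against 479 control-only sites. Inside genes the arms were closer, with 4074 case-only and 3725 control-only sites, or 52.2% case-only (exact 95% interval 51.1 to 53.4). Both intervals treat sites as independent, although 79.4% of case-only and 79.2% of control-only sites lay within 10 bases of another. They hold nothing of the spread between libraries, so they do not test the arms. The case-only sites fell in 1273 genes and the control-only sites in 1065.

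The genes with the most case-only sites were Agbl4, which encodes a tubulin carboxypeptidase (71 sites), Ctnna3, an alpha-catenin (54), Arsb, the lysosomal arylsulfatase B (47), Bhmt, betaine-homocysteine methyltransferase (41), Adgrl4, an adhesion receptor of endothelial cells (37), the long noncoding RNA 1700092C02Rik (34), Slc26a7, an anion transporter (32), Got1, the cytosolic aspartate aminotransferase (31), Gm13775 (30) and 1110004F10Rik (30). The 71 Agbl4 sites lay between 110408814 and 110409260 on chromosome 4, in a part of the gene without coding or UTR annotation, at a median level of 0.773 and a median coverage of 13. Bhmt carried its sites between 93754530 and 93766316 on chromosome 13 at a median level of 0.629 and coverage of 22. Library db_1 listed 38 of the 41 Bhmt sites and 29 of the 31 Got1 sites (median level 0.547), but 1 of the Arsb sites, 1 of the Gm13775 sites and 0 in each of the other 6 genes.

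Selenbp2, a selenium-binding protein gene, was 1 of the 10 genes with the most control-only sites and had 32 on chromosome 3 at a median level of 0.4095 and a median coverage of 131 reads. Gm37729 and Adh6-ps1, an alcohol dehydrogenase pseudogene, held 26 each. Taf4, a TFIID subunit gene, had 24 sites, all in coding sequence on chromosome 2. Phyh, the peroxisomal phytanoyl-CoA hydroxylase, had 23 (median level 0.663), Gm32006 and Ppia (cyclophilin A) 21 each, Tent4b 20, and Apoc2l 19. The 19 Apoc2l sites, between 19415045 and 19415092 on chromosome 7, are the same positions that the files also assign to Apoc4, so they cannot be credited to either apolipoprotein gene alone.

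Of the 3068 genes with a site, 203 held both case-only and control-only sites. That overlap was not tested against chance, because a gene enters the background only by having a site. Without db_1 the share of case-only sites was 60.1%.

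The second comparison asked where in transcripts the arm-only sites lay. Outside annotated genes lay 41.9% of case-only and 11.4% of control-only sites (odds ratio 5.61, two-sided Fisher exact test with Benjamini-Hochberg adjustment, adjusted p = 1.09e-277). Every class inside genes held a smaller share of the case-only sites. Coding sequence took 15.5% of case-only against 21.6% of control-only sites (odds ratio 0.668, adjusted p = 1.05e-15). The 5′ UTR took 8.14% against 14.9% (odds ratio 0.507, adjusted p = 6.85e-28), the 3′ UTR 6.00% against 10.3% (odds ratio 0.556, adjusted p = 4.53e-16), and parts of genes without coding or UTR annotation 28.4% against 41.7% (odds ratio 0.553, adjusted p = 9.90e-47). The test treats neighbouring sites as independent, although 79.4% of case-only and 79.2% of control-only sites lay within 10 bases of another. Among sites inside genes the odds ratio of coding sequence turned to 1.13 (adjusted p = 0.0338), that of the 5′ UTR was 0.807 (adjusted p = 0.00272), and those of the 3′ UTR (0.876) and of gene parts without annotation (1.07) did not pass. With each gene counted once per region, coding sequence turned to 1.25 (adjusted p = 0.0407) and the other classes inside genes did not pass. At coverage of at least 20 coding sequence (1.06) and the 3′ UTR (0.840) did not pass, and the odds ratio outside genes was 2.90; without clustered sites it was 2.34, and of the classes inside genes the 5′ UTR alone passed (0.616).

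**Figure D1:**
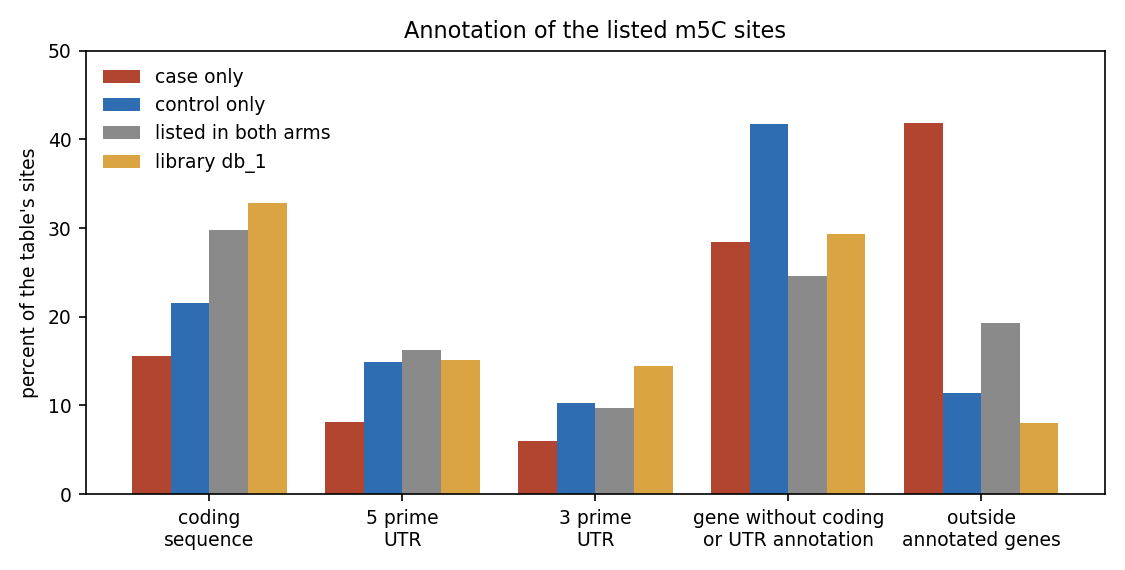
Percent of the sites of each table (vertical axis) in 5 annotation classes, for case-only, control-only, shared and db_1 sites; bars start at 0 and carry no error bars. The bars outside annotated genes stand at 41.9% for case-only, 11.4% for control-only, 19.3% for shared and 8.00% for db_1 sites.

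Levels of the arm-only sites differed with place as well. Case-only sites outside genes had a median level of 0.832 and those inside genes 0.406; for control-only sites the medians were 0.639 and 0.554. Over all arm-only sites the medians were 0.633 in case and 0.562 in control, and 11.9% of case-only against 2.52% of control-only sites stood at level 1. This order reversed among sites with coverage of at least 20 (0.345 in case, 0.439 in control) and of at least 30 (0.289 and 0.3525), and among sites with no neighbour within 10 bases (0.367 and 0.4175). The levels are arm means, so no test between libraries was made.

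The lists on fatty acids and on lipid droplets each had more genes with case-only than with control-only sites, as did all genes together (1273 against 1065). No gene list passed the test. Of the list of fatty acid and triglyceride synthesis, 10 genes had case-only and 3 control-only sites. Of fatty acid oxidation and ketogenesis, 5 genes had case-only sites (40 sites) and 0 control-only, and the same 5 against 0 stood for lipid droplets and lipolysis (6 sites). Two-sided Fisher exact tests of genes with case-only against genes with control-only sites gave p = 0.0672 for each of the latter lists (adjusted p = 0.739, the lowest of 22 lists) and p = 0.161 for synthesis. The 203 genes with both kinds of site count on both sides, which the test does not allow for.

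Within these lists, Cyp4a10, a fatty acid omega-hydroxylase, had 15 case-only sites on chromosome 4 between 115377950 and 115378170, and db_1 listed 13 of them. Their median level was 0.887 at a median coverage of 16, from 2 libraries at each site. No db_1 site had fewer than 8 C reads, so low levels may be missing at that depth. Acaa1b, a peroxisomal thiolase gene, had 5 case-only sites at a lower median level, 0.228, under a median coverage of 829. Acacb (acetyl-CoA carboxylase beta) had 5 in coding sequence (median level 0.287), and Srebf1, the master regulator of lipogenic genes, had 4 in coding sequence (0.2925) beside 4 control-only sites elsewhere in the gene (0.513). In cholesterol synthesis, Cyp51, lanosterol demethylase, had 9 control-only sites in its 5′ UTR (median level 0.269) and Fdps 3 case-only sites; 4 genes of the list had case-only and 5 control-only sites. In bile acid synthesis and transport the counts were 6 and 2, with 5 control-only sites each in Abcc2, the canalicular conjugate exporter, and Scp2, sterol carrier protein. The lists of lipoproteins and lipid transport (2 and 2 genes, with 11 control-only sites in Apoc1), glucose metabolism (5 and 2, with 15 case-only sites in Slc2a2, the hepatic glucose transporter) and insulin and leptin signalling (3 and 5) split without passing either.

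Lists outside lipid metabolism gave no call either. Genes with case-only and control-only sites numbered 4 and 0 for cytochromes P450 and conjugating enzymes, 8 and 4 for amino acid and urea metabolism (124 and 15 sites, with Bhmt and Got1), 5 and 6 for plasma proteins, 2 and 0 for the acute phase response, 2 and 3 for the nuclear-encoded respiratory chain, 3 and 0 for cytosolic ribosomal proteins, 3 and 0 for mitochondrially encoded genes, and 5 and 5 for the unfolded protein response. Markers of other liver cell types were sparse, with 4 and 1 genes for Kupffer cells and other leukocytes, 1 and 0 for stellate cells, 0 and 2 for endothelial cells, 0 and 1 for cholangiocytes and 1 and 0 for erythroid cells.

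**Figure D2:**
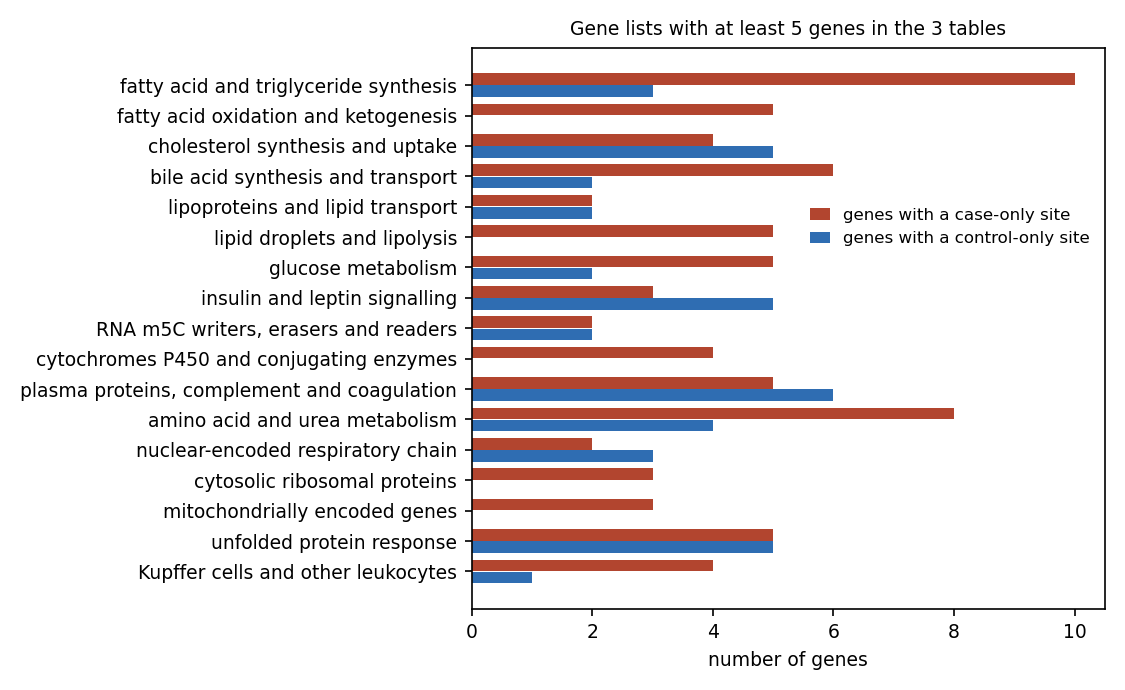
Number of genes (horizontal axis) with a case-only or a control-only site in the gene lists with at least 5 genes in the 3 comparison tables. Fatty acid and triglyceride synthesis has 10 and 3 genes, fatty acid oxidation and lipid droplets 5 and 0 each, and none of the lists passed the test.

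Of the writers, erasers and readers of RNA m5C, 6 had a listed site. Alyref, a reader that exports m5C-bearing mRNA, had 2 case-only sites (median level 0.353) and 13 shared sites in coding sequence on chromosome 11 between 120488986 and 120489087. Srsf2 had 2 case-only sites (median level 0.2255), Fmr1 1 control-only site in its 5′ UTR at position 67722336 of chromosome X (0.402, mean coverage 30), Tet3, a 5-methylcytosine oxidase, 7 control-only sites in coding sequence (0.54) and 1 shared site, Alyref2 2 shared sites and Tet2 a single site in db_1 (8 of 14 reads).

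The third comparison asked how levels differed at sites found in both arms. Levels were higher in case at 7398 of 10243 listed sites, lower at 1312 and equal at 1533, all of the last at level 1. The median difference, case minus control, was 0.08. It was 0.104 in coding sequence, 0.103 in the 5′ UTR, 0.094 in the 3′ UTR, 0.085 in gene parts without annotation and 0 outside annotated genes. Of the sites with unequal levels, 84.9% were higher in case. The authors' deposited table lists shared sites only with p below 0.05 in the authors' own test, so these shares describe a selected set.

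A two-sided Fisher exact test on the reads pooled per arm, with Benjamini-Hochberg adjustment, called 6381 sites higher and 633 lower in case; 3229 were not called. That test compares pooled reads and not animals, and in simulated data with the spread between libraries it called 18.1% of unchanged sites. limma's moderated test on mean levels and SDs, which sets the difference against the spread between libraries, called 4 higher and 0 lower of the 7552 sites with at least 2 libraries in each arm (2161 and 136 at an unadjusted p below 0.05). In the same simulated data it recovered 0% of changes of 0.1 and 39.6% of changes of 0.3, so a site without a call by limma is not shown to be unchanged. None of the sites in the gene lists passed it, and the calls in the lists below rest on pooled reads. Nothing in the labels says that the libraries came from separate animals, so its p-values measure the spread between these libraries, which may be technical.

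In fatty acid and triglyceride synthesis, 71 of 75 shared sites were called higher and 1 lower by the Fisher test (73 and 1 adjusted over the list alone), and 0 passed limma (9 higher and 1 lower at an unadjusted p below 0.05). The median difference of the list was 0.071, beside 0.08 over all shared sites. Its sites were deeper, at a median coverage of 324 in case and 261 in control, beside 53 and 76 over all shared sites. Deeper sites pass a test of pooled reads at smaller differences. Srebf1 was called higher at all 10 of its sites, in coding sequence on chromosome 11 between 60092522 and 60092630, with a median difference of 0.0775. At its 9 sites with 4 libraries in each arm, db_1 lay above the control mean at 0 and the mean of the other 3 case libraries at 9. Library db_1 did not list position 60092630. At position 60092630 the level was 0.335 ± 0.022 in case (SD, n = 3) and 0.230 ± 0.042 in control (SD, n = 4; limma adjusted p = 0.0925). Acacb was called higher at 9 of 9 sites (median difference 0.091). At its 8 sites with 4 libraries in each arm, db_1 lay above the control mean at 1 and the mean of the other 3 case libraries at 8. Fasn, fatty acid synthase, was called higher at 13 of 14 sites in its 3′ UTR and coding sequence and lower at position 120698575, but its differences were small beside the spread: at position 120704696 the level was 0.431 ± 0.096 in case (SD, n = 4) and 0.427 ± 0.118 in control (SD, n = 4), and by limma 1 Fasn site was higher and 1 lower at an unadjusted p below 0.05. Without db_1 the lower call of Fasn was lost. At the 14 Fasn sites db_1 lay above the control mean at 4 and the mean of the other 3 case libraries at 13. At the 48 sites of this list found in 4 libraries of each arm, db_1 lay above the control mean at 10, and the mean of the other 3 case libraries at 47.

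In cholesterol synthesis and uptake, 24 of 42 shared sites were called higher and 2 lower (24 and 2 adjusted over the list alone), and 0 passed limma (10 higher and 0 lower at an unadjusted p below 0.05); without db_1 no site was called lower. At the 11 sites of the list with 4 libraries in each arm, db_1 lay above control at 3 and the mean of the other 3 case libraries at 10. Fdps, farnesyl diphosphate synthase, was higher at all 9 sites, between 89008341 and 89008357 on chromosome 3, with a median difference of 0.248, and of its 6 sites open to limma 0 passed and 5 had an unadjusted p below 0.05. Library db_1 listed only position 89008341, at 0.242 beside a control level of 0.207. The other Fdps sites had 2 case libraries each. Control levels ran from 0.207 to 0.284, near the lowest level of 0.2 in db_1. Libraries under such a level would be missing from the arm means. At position 89008353 its level was 0.507 ± 0.074 in case (SD, n = 2) and 0.233 ± 0.027 in control (SD, n = 3; limma adjusted p = 0.0776), at a mean coverage of 51 and 80 reads. Srebf2, the regulator of cholesterol synthesis, stood at level 1 in both arms at all 13 of its shared sites. These lay between 82049102 and 82049132 on chromosome 15, and db_1 listed none of them. They rested on 2 case libraries at 11 to 12 reads and 1 control library at 16 to 18 reads. In fatty acid oxidation and ketogenesis 7 of 8 sites were called higher (8 adjusted over the list alone; 0 by limma, 2 at an unadjusted p below 0.05), Acaa1b among them.

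In lipid droplets and lipolysis 28 of 32 sites were called higher and 0 lower (28 adjusted over the list alone; 0 by limma, 9 higher at an unadjusted p below 0.05). Fitm2, a lipid droplet biogenesis protein, was called higher at 9 of 9 sites of its 3′ UTR (median difference 0.078), Cideb at 6 of 6 (0.036) and Plin5 at 4 of 5 (0.069); by limma 0 sites of these genes passed, and 4, 0 and 1 had an unadjusted p below 0.05. In lipoproteins and lipid transport 43 of 61 were called higher and 5 lower (45 and 5 adjusted over the list alone; 0 by limma, 9 higher and 1 lower at an unadjusted p below 0.05). There, Apoc1 was called higher at 17 of 21 sites and lower at 1 (median difference 0.133), the positions assigned to both Apoc4 and Apoc2l higher at 6 of 7, and Lrp1 higher at 7 of 12 and lower at 3. The lower call of Apoc1 was lost without db_1. Library db_1 lay above control at 12 of the 23 lipid droplet sites with 4 libraries in each arm and at 7 of the 26 lipoprotein sites, against 23 and 25 for the mean of the other 3 case libraries. At such sites db_1 lay above control at 8 of 9 in Fitm2, 0 of 6 in Cideb and 0 of 3 in Plin5. It did so at 0 of 9 in Apoc1, 0 of 3 in Lrp1 and 0 of the 6 assigned to both Apoc4 and Apoc2l. In the same order, the mean of the other 3 lay above control at 9, 6, 3, 8, 3 and 6.

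In bile acid synthesis and transport 11 of 16 sites were called higher and 1 lower (12 and 2 adjusted over the list alone; 0 by limma, 2 higher and 1 lower at an unadjusted p below 0.05). Slc27a2, a bile acid and fatty acid acyl-CoA ligase, was called higher at 10 of 12 sites (median difference 0.051). Abcc2 was called lower at 1 of 3, position 43775400, at 0.473 ± 0.125 in case (SD, n = 4) and 0.630 ± 0.088 in control (SD, n = 4), where db_1 read 0.3; without db_1 none of the 3 was called lower and 1 was called higher. Scp2 had 1 shared site, called higher (1 against 0.334), whose case value was that of db_1 alone at 10 reads.

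In glucose metabolism 10 of 33 sites were called higher and 7 lower (10 and 6 adjusted over the list alone; 0 by limma, 2 higher at an unadjusted p below 0.05). All 7 lower calls were in G6pc1, the catalytic subunit of glucose-6-phosphatase, between 101265805 and 101265823 of chromosome 11, where a CA repeat puts a listed site at every other base. Its control values there came from 1 library, and without db_1 no G6pc1 site was called, which left 9 sites called higher and 0 lower over the list. Slc2a2 was called higher at 1 of 2 sites, and at 0 without db_1.

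**Figure D3:**
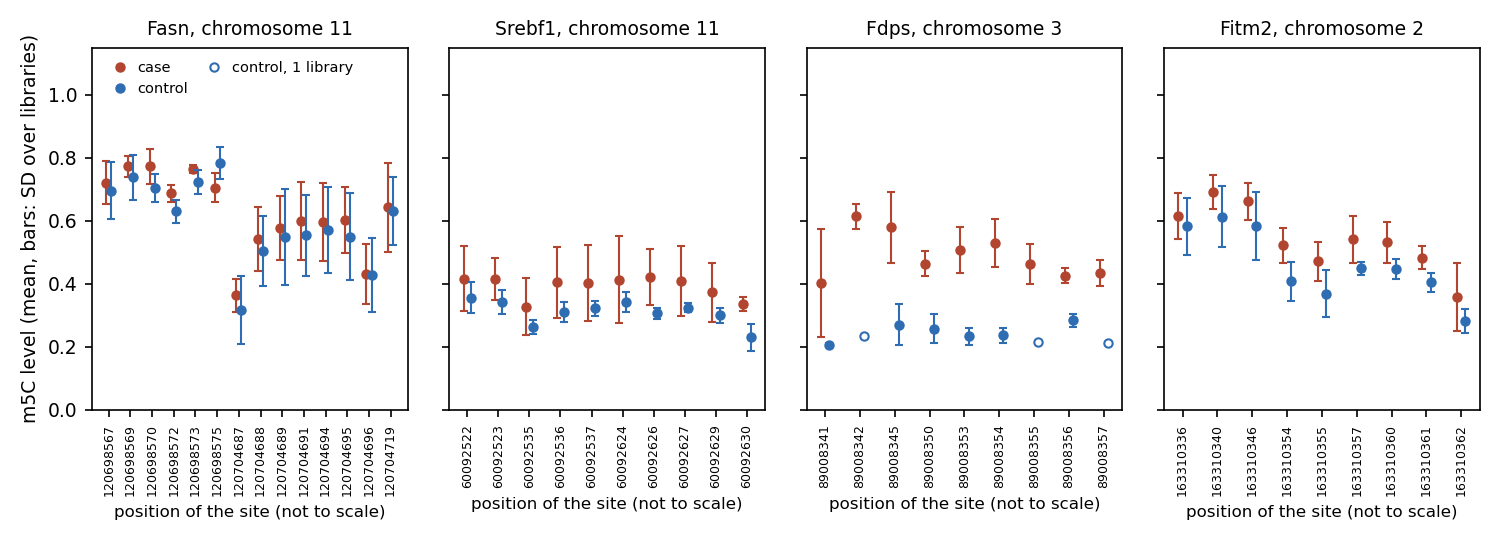
Mean m5C level (vertical axis) at each shared site of Fasn, Srebf1, Fdps and Fitm2 in position order (horizontal axis, not to scale) in the case and control arms; bars are the SD over libraries and open symbols are values of 1 library. Fdps, with 1 to 3 libraries per arm, separates by a median of 0.248, Srebf1 by 0.0775, Fitm2 by 0.078 and Fasn by 0.037.

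Most other lists also had more sites called higher than lower, and limma called 0 sites in each. Sites called higher and lower numbered 49 and 0 of 50 in the nuclear-encoded respiratory chain (50 and 0 adjusted over the list alone; by limma 7 higher at an unadjusted p below 0.05), 31 and 0 of 36 in amino acid and urea metabolism (33 and 0; 14 higher unadjusted), 23 and 2 of 30 in insulin and leptin signalling (23 and 2; 11 higher unadjusted), 21 and 1 of 26 in cytochromes P450 and conjugating enzymes (21 and 1; 10 higher unadjusted), 10 and 0 of 12 in cytosolic ribosomal proteins (11 and 0; 1 higher unadjusted), 19 and 3 of 26 in the unfolded protein response (21 and 3; 5 higher and 2 lower unadjusted) and 9 and 0 of 10 in Kupffer cells and other leukocytes (10 and 0; 2 higher unadjusted). At sites with 4 libraries in each arm, db_1 lay above control at 5 of 43 in the respiratory chain, 0 of 6 in cytochromes P450, 1 of 8 in ribosomal proteins and 11 of 14 in amino acid and urea metabolism, and the mean of db_2 to db_4 at all of them. The single endothelial site was called higher and the single acute phase site was not called. Of the m5C machinery, 13 of 16 sites were called higher and 0 lower (14 adjusted over the list alone; 0 by limma, 7 at an unadjusted p below 0.05), with 11 of 13 in Alyref (median difference 0.149) and 2 of 2 in Alyref2; the Tet3 site was not called.

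Plasma proteins, complement and coagulation went both ways, with 10 sites called higher and 12 lower of 30 (10 and 12 adjusted over the list alone; 0 by limma, 6 higher and 4 lower at an unadjusted p below 0.05), and 7 lower without db_1. Of the 14 shared sites in mitochondrially encoded genes 3 were called lower and 0 higher (3 adjusted over the list alone; by limma 0 passed, and 0 had an unadjusted p below 0.05). Fisher exact tests of whether a list's genes leaned apart from the other genes passed for none of the lists (lowest p = 0.0193 for mitochondrially encoded genes, adjusted p = 0.424).

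The 10 largest rises ran from 0.599 to 0.697 and lay in Sort1, the sortilin gene, Slc37a1, Scp2, Mcrip2, Mepce, Mtor, Slc66a2, Ppp3cc and at 2 sites outside genes. The largest was Sort1, position 108191651 of chromosome 3 in coding sequence, at 1 in case (1 library, 13 reads) and 0.303 ± 0.071 in control (SD, n = 2; 69 reads). The 10 largest falls ran from -0.499 to -0.616 and lay in Col18a1, Atl3 and Cant1 (2 sites each for the latter pair), Snx5, Rbp4, the plasma retinol carrier, Nrarp and 2 sites outside genes on chromosome 14. All 20 rested on 1 library in at least 1 arm, so none was open to limma. The value of db_1 was the whole case value at Scp2, Slc37a1, Ppp3cc, Atl3, Cant1, Rbp4 and 1 of the rises outside genes. The arm with the higher level was always shallow, with 10 to 21 reads in case at the rises and 11 to 19 in control at the falls. No db_1 site had fewer than 8 C reads, so low levels may be missing at such depths. The ranking may therefore reflect which levels could be listed.

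Among sites found in 4 libraries of each arm, picked after their values were seen, the 10 largest rises and 10 largest falls held 1 site that passed limma, in the 5′ UTR of Zfpm1, a GATA cofactor gene. At that site, position 123009170 of chromosome 8, the level was 0.584 ± 0.032 in case (SD, n = 4) and 0.314 ± 0.045 in control (SD, n = 4; limma adjusted p = 0.0438). The others included Siah2, a ubiquitin ligase gene, at 0.697 ± 0.095 in case (SD, n = 4) and 0.399 ± 0.102 in control (SD, n = 4; limma adjusted p = 0.0762). Of the falls, Vasp at position 19005487 of chromosome 7 stood at 0.507 ± 0.037 in case (SD, n = 4) and 0.705 ± 0.111 in control (SD, n = 4; limma adjusted p = 0.0925), and Cebpa, a hepatocyte transcription factor gene, at 0.502 ± 0.119 (SD, n = 4) and 0.697 ± 0.081 (SD, n = 4) at position 34820530 of its 3′ UTR (limma adjusted p = 0.123). Leaving out db_1 ended the Fisher calls of Sts at both of its sites, Rgp1 and Samd8.

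Library db_1 lay closer to control than the mean of the other case libraries did. At the 3632 sites it shared with 4 libraries of each arm, its level exceeded the control mean by a median of 0.024 and lay above it at 59.4%, while the mean of db_2 to db_4 exceeded control by 0.091 and lay above it at 94.3%. At the 679 of these sites with fewer than 30 reads in db_1 the medians were 0.102 and 0.113, with 76.6% and 90.7% of sites above control. They were 0.043 and 0.0947 at the 1629 sites with at least 30 and under 100 reads, and -0.010 and 0.0773 at the 1324 sites with at least 100, where 44.0% and 97.1% lay above control. The table of db_1 lists no site with fewer than 8 C reads, so at low coverage only high levels of db_1 enter, and the sites with at least 100 reads are the least affected. In the 5′ UTR the shares above control were 65.2% for db_1 and 93.6% for the mean of db_2 to db_4, and in the 3′ UTR 48.2% and 88.9%. A single library scatters more than a mean of several, so its share above control is lower even at an equal rise. Median coverage was 69 in db_1, 151.5 as the mean of the other 3 and 194 in control.

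**Figure D4:**
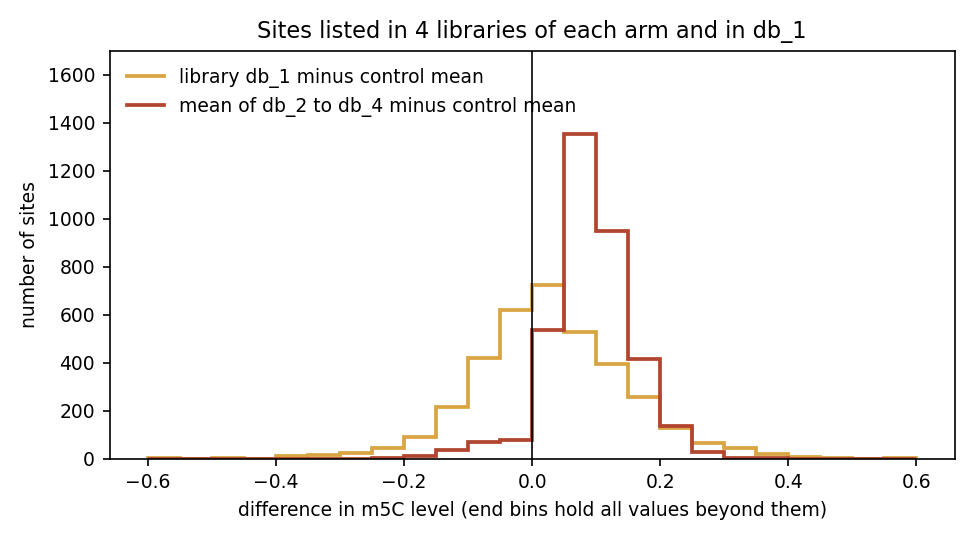
Number of sites (vertical axis) by the difference in m5C level from the control mean (horizontal axis), for db_1 and for the mean of db_2 to db_4, at 3632 sites listed in 4 libraries of each arm and in db_1. The distribution of db_1 is centred at 0.024 and that of the mean of db_2 to db_4 at 0.091.

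The sites of db_1 by themselves fell mainly in genes. Coding sequence held 32.8% of its 21164 sites, parts of genes without coding or UTR annotation 29.3%, the 5′ UTR 15.1%, the 3′ UTR 14.5% and sequence outside annotated genes 8.00%. The genes with the most sites were the mitochondrial genes mt-Nd5 (292 sites, median level 0.716), mt-Nd4 (165, 0.573) and mt-Nd2 (113, 0.512), all subunits of respiratory complex I, and then Zftraf1 (100), Got1 and Isoc2a (88 each), Gm45808 (87), Dhdh (78), Irf2bp2 (77) and Bhmt (63). Gm45808 and Dhdh overlap between 45122019 and 45134701 on chromosome 7, so their counts share sites.

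Of sites with coverage of at least 30, 141 of 12452 stood at level 1. The 10 deepest of these were 6 sites of mt-Nd5, from position 11794 to 11852, 1 in the 5′ UTR shared by Cenpb and Spef1 (199 of 199 reads, Wilson 95% interval 0.981 to 1), 1 each in Nectin2 (77 of 77 reads) and Atp13a3 (72 of 72 reads), and 1 outside genes on chromosome 8 (65 of 65 reads). The deepest, position 11852 of the mitochondrial chromosome, had 220 of 220 reads with C (Wilson 95% interval 0.983 to 1). All 10 lay within 10 bases of another site. Sequence context was read only from the windows printed in the db_1 table. A cytosine followed after 1 base by GGG, the motif of the methyltransferase NSUN2, made up 7.08% of the db_1 sites (Wilson 95% interval 6.74 to 7.43) and 4.98% of the other cytosines of the same windows (4.80 to 5.16). Isolated sites had it more often than clustered ones (9.06% and 6.75%, odds ratio 1.38, two-sided Fisher exact p = 8.79e-06). Bases within 5 of a site were G or C in 72.3%.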

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

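The tests below on the control library, on loci with both strands and on db_1 listing were chosen after the results were seen; the opposite-strand share was the test set beforehand. The 3 signals given first stand out in the db_1 table, which holds them outside the comparison of the arms.

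The mitochondrial chromosome of db_1 held 891 sites, 823 on the plus strand, at a median level of 0.658 and a median coverage of 302; 98.3% lay within 10 bases of another site. Of these, 100 were also case-only sites, 14 shared and 0 control-only. Mutated reads, which carry neither C nor the converted base, occurred at 210 db_1 sites (0.992%), with up to 338 reads at 1 site and a share of at least 10% at 10 sites. None of the comparison tables listed 14998 db_1 sites (70.9%); a site needs a second case library or p below 0.05 in the authors' test to enter them.

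The excess of case-only sites outside genes is the pattern most worth following up, since db_1 lists few of them. Of the 2935 such sites found in 2 or 3 case libraries, db_1 listed 126 (4.29%), and of the 3934 in genes 843 (21.4%). Libraries that are alike would list 50% of sites in 2 and 75% of sites in 3. Transcription outside genes common to all 4 case libraries is left open by this, since db_1 was also the shallower library. Shared sites whose control value rests on 1 library at 40 reads or more numbered 760, and 563 had a high ratio of the authors' scaled to unscaled coverage (median 1.25), taken here to mark 1 library; of these 58.8% stood at level 1, 60.7% lay outside genes and 83.8% lay in exactly the 3 case libraries other than db_1, so unconverted sequence in these 4 libraries is a candidate explanation. For genomic DNA, the outcome set beforehand against it was an opposite-strand share at or below that of control-only sites in genes. The share did lie below it, but the exact intervals overlapped, so genomic DNA was left open. Of case-only sites outside genes, 0.306% (exact 95% interval 0.140 to 0.581) had a case-only site on the opposite strand within 100 bases. The share was 0.671% (0.435 to 0.989) for control-only sites in genes and 2.71% for control-only sites outside genes. With neighbours joined by gaps of at most 100 bases, 4 of 452 case-only loci outside genes had both strands (0.885%, exact 95% upper limit 2.25%). Of control-only loci in genes 5 of 1272 did (0.393%), a difference within the spread (two-sided Fisher exact p = 0.253). DNA read evenly from both strands stays open too. The search covered case-only sites alone, so an opposite-strand site listed in both arms could not be counted. A biological difference between the mice stays open and was not tested.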

How the results depend on the processing

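No paired analysis was run, because the comparison tables used here carry arm means and no values per library. For the same reason only db_1 was left out, other splits of the libraries were not run, and the replicate block and pseudocount alternatives were not run. Settings on annotated genes, level 1, libraries per site, limma, 4 libraries per arm, unclustered shared or isolated context sites and db_1 for levels, regions and lists were chosen after seeing the data. Of the main results, 45 values under other settings kept direction and side of the threshold or moved little, 26 moved, 6 weakened and 6 reversed. Some of the 45 could not change. All arm-only and db_1 sites already met the level of at least 0.2, and the median difference does not depend on the logistic model. The cause was not tested unless said.

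The percent of arm-only sites that are case-only was 57.3 at coverage of at least 20, 61.4 at 30, 60.1 without db_1, 52.2 in annotated genes, 60.1 without level-1 sites, 66.3 with at least 3 libraries and 54.4 counting genes. Sites called higher and lower numbered 3816 with a difference of at least 0.1 (higher), 419 at coverage of at least 30 (lower), 4 and 0 by limma (2161 and 136 at an unadjusted p below 0.05), which tests fewer sites against the spread between libraries, 3232 and 175 with 4 libraries in each arm and 873 and 164 without clustered sites; the last 2 and the coverage setting test fewer sites. Median levels of case-only sites were 0.345, 0.289, 0.367 and 0.406 (coverage 20, coverage 30, unclustered, in genes), and of control-only sites 0.439, 0.3525 and 0.4175 for the first 3.

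Counting each gene once per region gave odds ratios of 1.25 for coding sequence (adjusted p = 0.0407, reversed), 0.874 for the 5′ UTR, 1.13 for the 3′ UTR (reversed) and 0.846 for gene parts without annotation. Without clustered sites coding sequence gave 0.822, the 3′ UTR 1.07 (reversed) and gene parts without annotation 0.849. At coverage of at least 20 coding sequence gave 1.06 (reversed) and the 3′ UTR 0.840. In annotated genes alone coding sequence gave 1.13 (reversed), the 3′ UTR 0.876 and gene parts without annotation 1.07 (reversed). The odds ratio outside genes ran from 2.34 to 6.37. No gene list passed in any (lowest adjusted p from 0.509 to 1).

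The db_1 table kept 12452 sites at coverage of at least 30 and 3034 unclustered; G or C around its sites was 74.5% within 2 bases and 61.4% at isolated sites. Of the named shared sites with 4 libraries in each arm, 1 kept the call by limma and 19 lost it, and leaving out db_1 ended 4 and kept 17 of the 21 calls of named shared sites that held it beside other case libraries; 9 more had the value of db_1 alone and 10 did not hold it. With the spread between libraries simulated, the Fisher test recovered 56.0% of sites changed by 0.1 and called 18.1% of unchanged ones, and limma 0% and 0.0136%.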

Other observations

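The tests of selection, coverage, db_1 and a common rise were chosen after the result was seen; those on reads and levels of genes with arm-only sites were set beforehand. The genes and sequences named first were also chosen after their values were seen.

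By the Fisher test on pooled reads, outside the lists the most sites called higher were in Wdr26, a subunit of a ubiquitin ligase complex, which was called higher in case at 33 of 33 shared sites (median difference 0.147), Zftraf1 at 32 of 42 (0.11), Irf2bp2, a transcriptional corepressor gene, at 31 of 38 (0.0955), Gas1 at 28 of 31 (0.108) and Nr2f6, an orphan nuclear receptor gene, at 28 of 31 (0.056). The most sites called lower were in Rn18s-rs5, a ribosomal RNA pseudogene (57 lower and 13 higher of 93), Mir6236 (13 of 13, median difference -0.107), Cebpa (11 lower and 15 higher of 26) and Vps26c (10 of 10 in the 3′ UTR, -0.1). limma called 0 sites in these 9 genes; at an unadjusted p below 0.05 it had 8 higher in Wdr26, 8 in Zftraf1, 17 in Irf2bp2, 18 in Gas1 and 1 in Nr2f6, 1 higher in Rn18s-rs5, 1 higher and 1 lower in Cebpa and 1 lower in Vps26c, and no Mir6236 site was open to it. Reads of ribosomal RNA copies cannot be assigned to 1 of them.

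Some db_1 sites repeat 1 sequence at many places. The window CACACACACACACACACACAC accounted for 74 sites on 5 chromosomes at a median level of 0.871, and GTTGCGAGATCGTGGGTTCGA for 50 sites on 13 chromosomes, all outside annotated genes, at a median level of 0.727. In the G6pc1 window reported above, db_1 read between 0.5 and 0.614 at the 7 called sites.

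The rise of levels in the case arm at shared sites did not come from db_1, since without it the median difference, case minus control, was 0.09 beside 0.08 with it. Selection of sites by p stays open. The 84.9% of sites with unequal levels that were higher in case is the pattern itself and does not test it. Lower coverage in case is argued against at the 2141 sites with at least 100 reads in both arms and 4 libraries in each. There the median difference was 0.06 and 95.8% were higher. At shallower sites lower coverage in case stays open as a source of part of the rise. At the 679 sites with 4 libraries in each arm where db_1 was shallowest (median coverage 20), db_1 exceeded control by a median of 0.102. The mean of the other 3 case libraries exceeded control there by 0.113. Where db_1 had at least 100 reads, the sites least affected by its minimum of 8 C reads, it lay above control at 44.0% (median difference -0.010) and the mean of the other 3 case libraries at 97.1% (0.0773). Whether all 4 case libraries share a rise stays open. Library db_1 did not show it at those sites, but it is the only library with values of its own in the data used here, and 1 library does not settle it. A difference between the mice of the arms stays open.

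Whether a gene holds case-only or control-only sites could come from more reads of it in the arm that lists it. It could also come from higher levels in that arm. The overlap of 203 genes with both was not tested against chance. At shared sites, genes with case-only sites (382) had a median log2 ratio of case over control coverage of -0.55 and genes with control-only sites (207) of -0.69; the difference, 0.141 (bootstrap 95% interval -0.0598 to 0.281, permutation p = 0.133), excludes the 0.5 named beforehand for the first explanation but not the 0.2 under which it was to be ruled out, so a smaller difference in reads stays open. The median difference in level was 0.102 in the former and 0.131 in the latter, a difference of -0.0295 (interval -0.0575 to -0.013, permutation p = 0.0007), opposite to higher levels in the arm that lists a site. The prediction had named a size and no sign. Both intervals and both permutation tests resample genes and hold nothing of the spread between libraries, so they do not test the arms. The shared sites behind them were also selected by the authors' p. Whether the abundance of these transcripts differed was not measured in the tables used here.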
